A study of Rattus norvegicus with 24 samples.

How the data were processed

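RNA from 24 samples of RBEC4, a line of rat brain microvascular endothelial cells used as a model of the blood-brain barrier, was measured on Illumina rat expression BeadChips. Per the labels, cells at 95% confluence were exposed for 18 h to 1 ppm of silver nanoparticles. The particles had a nominal size of 10 or 75 nm and a coating of polyvinylpyrrolidone (PVP) or citrate. The groups are written here as control, PVP10, PVP75, citrate10 and citrate75. They held 4 control arrays and 5 arrays for each particle. The labels number the arrays within a group and do not say whether they came from separate cultures or days, so p-values measure only the spread between these samples, which may be technical. RNA was extracted with a column kit with DNase treatment and amplified into biotinylated cRNA, per the labels' protocols.

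The deposited table of signals holds, per the file headers, a bead intensity on a linear scale for each of 22523 probes on each array. Its values are neither background-subtracted nor normalized, as read from the values. Beside each intensity the deposited table gives a detection p-value, per the file headers. It runs in steps of 1 in 825, as read from the values. GenomeStudio 2011.1 is named in the submitters' processing notes, and further steps are not given in the sources used here. A further deposited table of intensity values on a linear scale had the same quantiles on every array, with a column median between 88.85 and 88.88, so these values were quantile normalized by the authors without background subtraction. It served as an alternative. Every array column was tied to its sample through the chip name and position in the labels, and 0 sample columns were left unused.

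Background was corrected by normexp convolution with the negative control distribution inferred from the detection p-values (limma 3.58.1, R 4.3.3), with an offset of 16. The values were then quantile normalized over all probes and taken to log2. A probe was kept when its detection p was under 0.01 on at least 4 arrays, the size of the smallest group. This left 2774 probes, 12.3% of the array. Between 2128 and 2576 probes were detected per array at that threshold, so most probes gave no signal above background, and a gene whose probe was not detected has no measured level here. The number of arrays limits the precision. The median standard error of a log2 fold change lay between 0.104 and 0.117 in the comparisons of a pair of groups. Levels are normalized log2 intensities and are compared only within a probe. A probe not detected on any array of a group has only a bound there. Its fold was computed against the lowest level of a detected probe on each array, or its own level if higher, and is written as at least that size.

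Probe names came from the platform's annotation, which can be old. It gives 1 gene symbol to 13793 probes, several to 0 and none to 8730, which are unnamed here. The Entrez identifiers of 13752 named probes were found in a reference table of the GRCr8 assembly, which changed 0 symbols. Of the kept probes 1968 had a symbol. A gene with several kept probes was represented by the one with the highest mean over all arrays, which left 2748 tested entries (1942 named genes and 806 unnamed probes), called probes below. Of the 22 genes with several kept probes, 6, Nck2 among them, had probes that differed in the PVP10 call and 0 had probes called in opposite directions.

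A linear model with the 5 groups and the BeadChip as fixed terms was fitted to all 24 arrays with limma (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the 2774 kept probes within each comparison. A probe with an adjusted p under 0.05 is written as called. Each of the 2 BeadChips held all 5 groups, unevenly. Chip 1 held 1 control, 2 PVP10, 4 PVP75, 2 citrate10 and 3 citrate75 arrays. The comparisons were each particle against control, the sizes within a coating, the coatings within a size, the interaction of size and coating, PVP10 against the mean of the other 3 particles, and any difference among the 5 groups (F test). The chip term was called for 31 probes. Fold changes of a comparison that spans chips are adjusted for the chip, and group means are not.

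Before the data were examined, 33 gene lists were fixed, and the 14 with at least 5 kept members were tested with limma's camera at a preset correlation of 0.01, adjusted over 14 lists and 10 comparisons. Camera with an estimated correlation and fry (rotation test of one direction) were run beside it. Named genes followed a rule fixed at the same time. It took the 10 called genes with the largest rise and the 10 with the largest fall, if detected on every array of the higher group, up to 4 called members of each list by size of change, a panel of 23 stress, inflammation and barrier genes whatever their result, and the 3 smallest p-values where a comparison had fewer than 5 calls. Placeholder names were counted and not named. Similarity of the particle profiles was Pearson's r across probes, with values from 100 simulations of unchanged groups against the same controls, and from every split of the 4 controls between the 2 particles. The slope and same-sign share over called probes were set beside 100 simulations with the PVP10 changes kept and PVP75 unchanged, chosen after seeing the data.

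On simulated data for PVP10 vs control, with 2748 probes of which 200 were changed, the model recovered 89% of the 100 probes changed by 0.5 log2 units and 100% of the 100 changed by 1 log2 unit. Of its calls 4.33% were unchanged probes. A planted list of 20 probes shifted by 0.3 gave a camera p of 4.04e-10 and an unchanged list gave 0.981. Errors were drawn independently for each probe, so the simulation cannot check the preset correlation of the list tests. In the simulated PVP75 profile, planted at 0.4 times the PVP10 changes, the slope over called probes came out at 0.413. The simulated citrate75 group, left unchanged, gave 0 calls.

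The alternatives tried were no background correction (values under 16 set to 16), an offset of 50, cyclic loess, no filter, detection on all 24 arrays, no chip term, the chip as a random block, each chip alone, a block for the replicate number, the compared groups alone, array weights, the authors' normalized values, leaving out each array in turn, and other list tests. Chosen after seeing the data were quantile normalization over the kept probes, all counts and list tests without PVP75 replicate 3, and PVP10 vs citrate10 set beside PVP75 vs citrate75, which share no array. Identical signals were found on 0 arrays. Figures were drawn with matplotlib.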

Results

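Expression was measured in RBEC4 rat brain endothelial cells, which model the wall of brain capillaries, 18 h after exposure to 1 ppm of silver nanoparticles. The particles differed in nominal size, 10 or 75 nm, and in coating, polyvinylpyrrolidone (PVP) or citrate. There were 4 control arrays and 5 arrays each of PVP10, PVP75, citrate10 and citrate75, on 2 BeadChips that both held all 5 groups. Of 22523 probes, between 2128 and 2576 were detected per array, and 2748 probes, each standing for 1 gene or 1 unnamed transcript, were tested. Within a group, arrays correlated at r between 0.981 (PVP75) and 0.996 (citrate75) across the kept probes. The first principal component held 46.6% of the variance and set PVP10 apart, with a mean of -16.2 ± 1.07 (SD, n = 5). PVP75 lay between, at -1.95 ± 0.799 (n = 5), while controls were at 6.42 ± 0.898 (n = 4), citrate10 at 5.24 ± 1.04 (n = 5) and citrate75 at 7.76 ± 1.16 (n = 5).

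**Figure D1:**
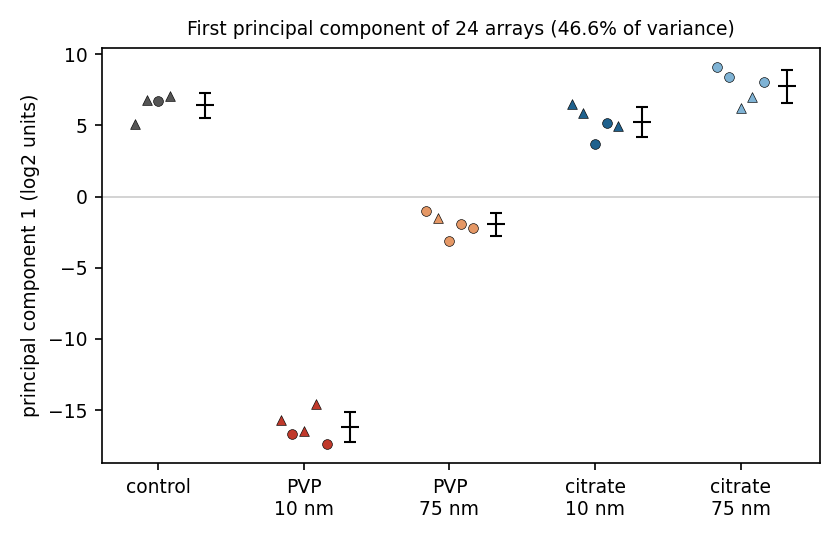
Score of each array on the first principal component of the normalized log2 intensities (vertical axis) by group (horizontal axis), with circles for chip 1, triangles for chip 2 and the group mean ± SD in black. PVP10 arrays sit near -16.2 and PVP75 arrays near -1.95, below the control, citrate10 and citrate75 arrays.

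The comparison of PVP10 with control asks what the small PVP-coated particles changed in these cells. The largest rises among named genes were in Slc1a2 and Sqstm1. Slc1a2, which encodes a glutamate transporter best known from astrocytes, rose 18.3-fold, from a log2 level of 5.37 ± 0.0843 (SD, n = 4) to 9.56 ± 0.525 (SD, n = 5). Sqstm1, which encodes the autophagy receptor p62, rose 8.19-fold (log2 fold change 3.03, SE 0.117, adjusted p = 7.61e-18). The largest falls were in the transcription factor gene Nfix (log2 fold change -2.33, SE 0.162), the spindle protein gene Fam83d (-2.15, SE 0.102), the zinc importer gene Slc39a10 (-2.11, SE 0.106) and the homeobox gene Prrx1 (-1.96, SE 0.11).

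Other large rises in PVP10 were in the peptidase gene Lap3 (1.95), the mTORC1 inhibitor gene Ddit4 (1.63), the elongation factor partner Eaf1 (1.63), the ubiquitin-binding Zfand5 (1.60), the vesicle GTPase gene Rab10 (1.51), the conjugating enzyme gene Ugt1a6 (1.48) and the small heat shock protein gene Hspb1 (1.48). Crebrf was not detected on any control array and was at least 2.45-fold higher in PVP10. Large falls were also seen in Tmem158 (-1.77), the interleukin 1 coreceptor gene Il1rap (-1.63), Mxd3 (-1.51), the adaptor gene Nck2 (-1.43), Epb41l1 (-1.39) and the nuclear receptor gene Pparg (-1.39). A further probe of Nck2 was not called (-0.07, adjusted p = 0.66), while that of Sqstm1 was (2.52, adjusted p = 1.38e-14). In all, 1148 of 2748 probes (41.8%) were called by limma with Benjamini-Hochberg adjustment, 553 higher and 595 lower. Of these, 418 changed by over 1.5-fold and 95 by over 2-fold. Of the called genes named here, Slc39a10 and Adm were detected on 4 of 5 PVP10 arrays, Il1rap on 3 and Mxd3 on 2. Mt3 was detected on 3 of 5 PVP10 and 0 of 4 control arrays, and Hspa5, Phlda1 and Plk1 were detected on 3 of 4 control arrays. Arrays of both groups overlapped for Tjp1 and Mt3. All 81 called genes taken by the naming rule had the same direction on both chips. They were chosen by their calls over both chips together, so this is not an independent check. On chip 2 alone 1047 probes were called, while chip 1 held 1 control array and has no count here.

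**Figure D2:**
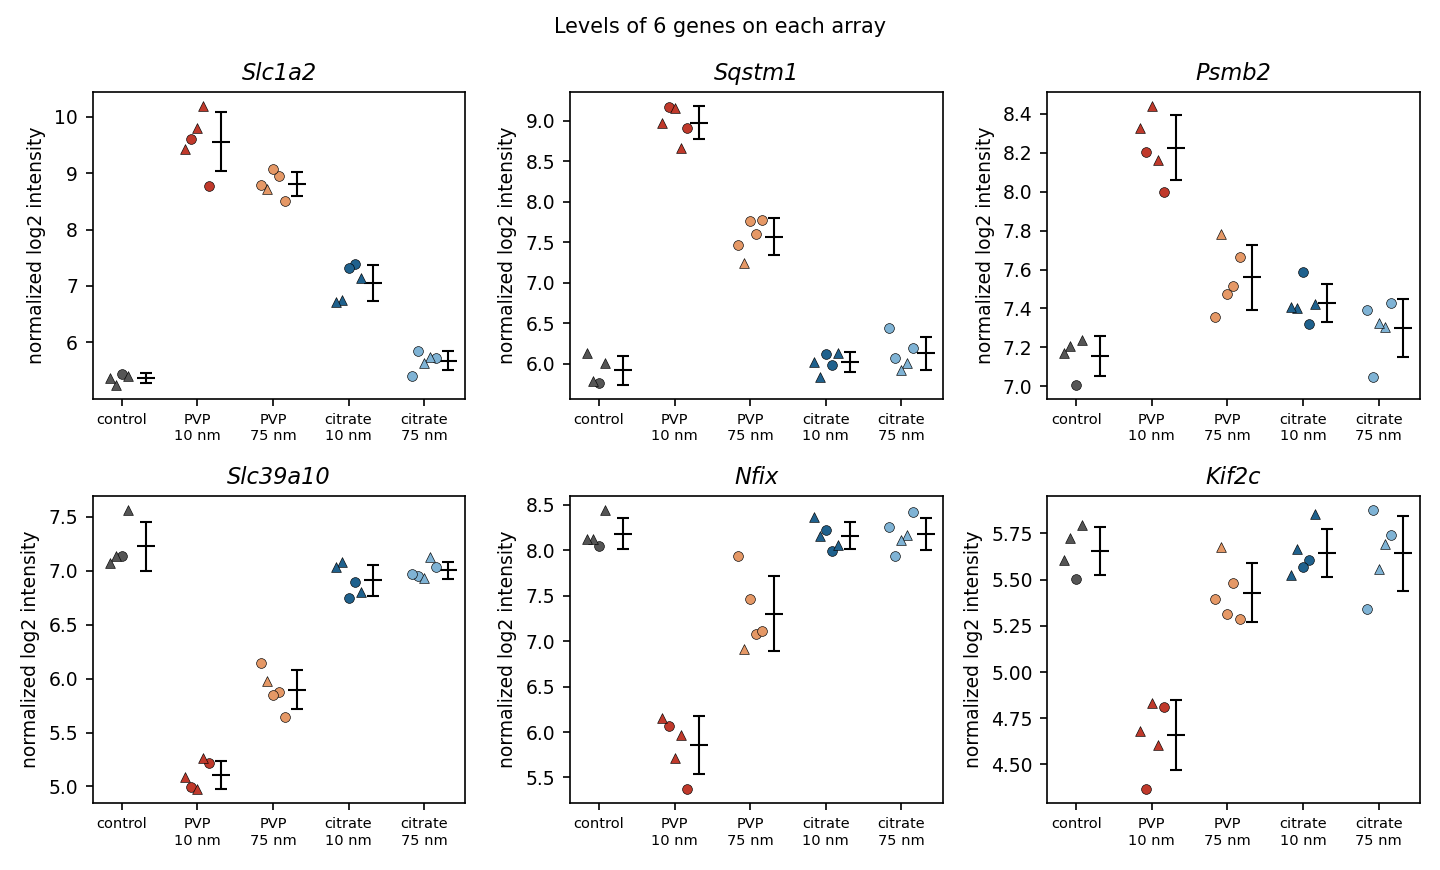
Normalized log2 intensity (vertical axes) of Slc1a2, Sqstm1, Psmb2, Slc39a10, Nfix and Kif2c on each array by group, with circles for chip 1, triangles for chip 2 and the group mean ± SD in black. Slc1a2 rises from 5.37 in control to 9.56 in PVP10, with PVP75 at 8.81 and citrate10 at 7.06.

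Proteasome genes rose together in PVP10. Of 19 measured subunits, 14 rose and 0 fell (14 also when adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 3.54e-05, and adjusted p = 0.00351 with an estimated correlation). Psmb2 rose by 1.09 (SE 0.0965), Psma1 by 0.99 (SE 0.133), Psmd13 by 0.84 (SE 0.138) and Psma2 by 0.78 (SE 0.132). The median shift was 0.60 on chip 1, which held 1 control array, and 0.44 on chip 2 (camera adjusted p = 0.000432).

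Of 10 lysosome and autophagy genes, 6 rose and 1 fell (8 called when adjusted over the list alone). Besides Sqstm1, which also belongs to the NRF2 list, the proton pump subunit gene Atp6v1b2 rose by 1.39, the lysosomal galactosidase gene Gla by 1.07 and the lysosomal membrane gene Lamp2 by 0.75. The list was called (camera adjusted p = 0.0015), but not with an estimated correlation (adjusted p = 0.0641 with an estimated correlation). Its median shift was 0.46 on chip 1, which held 1 control array, and 0.53 on chip 2 (camera adjusted p = 0.00439).

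Of 9 measured genes from the NRF2 list of oxidative stress targets, 6 rose and 2 fell (8 called when adjusted over the list alone). The glutathione transferase gene Gstp1 rose by 1.10 and the NADPH-forming malic enzyme gene Me1 by 1.09, whereas the carbonyl reductase gene Cbr3 fell by 0.85. Sqstm1, with a log2 fold change of 3.03, counts in this list and in the lysosome list, and neither was tested without it in any comparison. The camera test of the NRF2 list gave an adjusted p = 0.0285, and adjusted p = 0.077 with an estimated correlation. Its median shift was 0.29 on chip 1, which held 1 control array, and 0.33 on chip 2 (camera adjusted p = 0.0761). Of 6 genes of the endoplasmic reticulum stress list, 3 rose and 0 fell (3 when adjusted over the list alone), namely Herpud1 (0.80), a factor in the degradation of misfolded proteins, and the chaperone genes Canx (0.72) and Hspa5 (0.42). That list gave an adjusted p = 0.0384, and adjusted p = 0.262 with an estimated correlation. Its median shift was 0.56 on chip 1, with the lone control array, and 0.35 on chip 2 (camera adjusted p = 0.0761).

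Cell cycle genes went the other way. Of 15 measured members, 9 fell and 1 rose (10 called when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0455, and adjusted p = 0.107 with an estimated correlation). With the 4 members not detected on any array of a group at their bound, or at 0 where no bound could be given, the median was -0.13. The mitotic kinase gene Bub1 fell by 0.83 and the chromosome motor gene Kif22 by 0.68. The mitotic motor gene Kif2c was detected on 0 of 5 PVP10 arrays and was at least 1.65-fold lower, and the mitotic kinase gene Plk1 at least 1.10-fold lower. The median shift was -0.18 on chip 1, which held 1 control array, and -0.35 on chip 2 (camera adjusted p = 0.054).

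**Figure D3:**
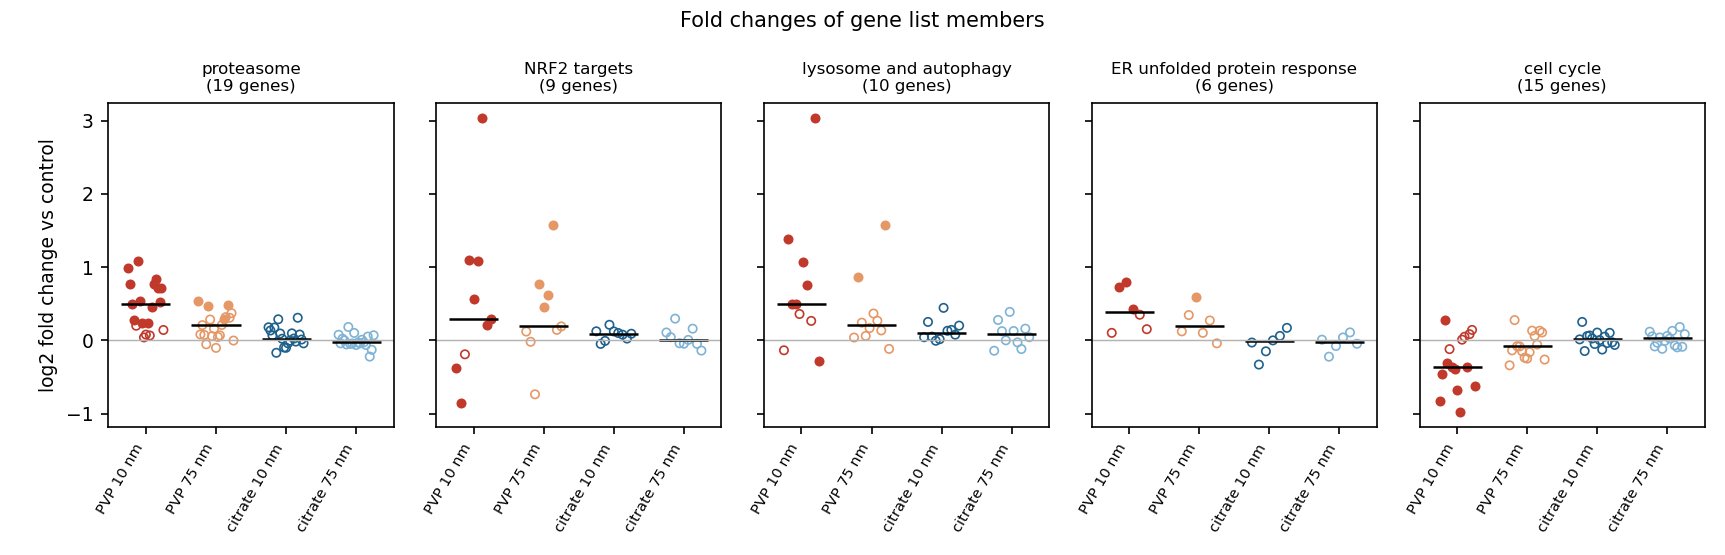
Log2 fold change against control (vertical axes) of each measured member of 5 gene lists for each particle, with filled points for called members and a bar at the list median. In PVP10 the proteasome median is 0.50 and the cell cycle median is -0.36.

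The other 9 tested lists were not called in PVP10. Each held called members, but 41.8% of all tested probes were called here, so such members do not set a list apart. For metal handling genes 3 rose and 1 fell (4 when adjusted over the list alone), with rises in the copper transporter relative Slc31a2 (0.45), the copper chaperone Ccs (0.35) and the metallothionein gene Mt3, which was at least 1.06-fold higher, beside the fall of Slc39a10. The measures of this list differed in sign, with a median of 0.34 (0.08 with Mt3 at its bound), a mean of -0.19, an upward direction in camera (adjusted p = 0.891) and a downward one in fry (adjusted p = 0.000732). The Mt3 call was lost without background correction. Among 7 hypoxia and glycolysis genes 3 rose and 2 fell (adjusted p = 0.756), with the vessel growth factor gene Vegfa up by 1.25 and the vasodilator peptide gene Adm down (-0.95). Among 9 immediate early genes 4 rose and 3 fell (adjusted p = 0.704), with rises in Phlda1 (0.93), Ier5 (0.79) and Junb (0.77) and a fall in Myc (-0.80). Among 16 endocytosis genes 3 rose and 4 fell (adjusted p = 0.729), with the early endosome gene Rab5a up by 0.93, the caveolar coat gene Cav1 down (-1.01) and the clathrin adaptor gene Ap2a1 down (-0.69). Of 23 ribosomal protein genes 7 rose and 1 fell (adjusted p = 0.13), among them Rpl13a (0.70).

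Of 15 oxidative phosphorylation genes 2 rose and 4 fell (adjusted p = 0.738), including Cox5a (0.54) and Atp5f1d (-0.52). Of 8 extracellular matrix and TGF-beta genes 1 rose and 3 fell (adjusted p = 0.697), the collagen gene Col5a1 by most (-0.82). Of 5 other antioxidant genes Gsto1 rose (0.92) and Prdx2 fell (-0.59) (adjusted p = 0.662), and of 5 apoptosis regulators Cflar fell (-0.57) (adjusted p = 0.71). Adjusted over the list alone, each of these 9 lists had as many called members as over all probes. Lists with under 5 measured members were not tested as lists. Of 17 heat shock genes on the array 4 were measured. All 4 rose, namely Hspb1, the cochaperone genes Dnaja1 (0.69) and Stip1 (0.34), and Hspb8, which was at least 1.28-fold higher. Hspb8 was detected on 5 of 5 PVP10, 2 of 5 PVP75 and 0 of 4 control arrays. It passed the filter only through PVP10, so its rise adds little. The sterol synthesis gene Sqle rose by 0.82, and Irf7 (-0.62), Epha2 (-0.66) and Phlda3 (-0.58) fell. The endothelial anticoagulant gene Thbd was called lower (adjusted p = 0.0224), but it was detected on 2 of 4 control and 0 of 5 PVP10 arrays, its fold had no bound above 1, and the call was lost with an offset of 50.

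Of the panel of 23 stress, inflammation and barrier genes, only Tjp1, which encodes the tight junction scaffold ZO-1, was measured. It fell in PVP10 by 0.36 (SE 0.095, adjusted p = 0.0029), below the control mean on 5 of 5 arrays. Cldn5 was detected on 1 array, 18 genes, among them Hmox1, Nqo1, Mt1a and Ocln, on 0 arrays, and 3 had no named probe here, so their levels were not measured. Markers of other cell types were also looked at. Of 9 astrocyte markers on the array 1 was measured, Slc1a2 itself. Of 14 neuron markers 3 were measured, with Gad2 at -0.39 (adjusted p = 0.00717), Nefm at 0.25 (adjusted p = 0.047) and Rbfox3 at -0.06 (adjusted p = 0.741) in PVP10. None of the pericyte, fibroblast, microglia, oligodendrocyte or choroid epithelium markers was measured. Few genes of endothelial cells themselves were measured either, with 3 of 26 endothelial identity genes on the array, 1 of 18 junction genes and 2 of 24 brain endothelial transporter genes. Undetected markers therefore do not show that other cell types were absent.

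The comparison of PVP75 with control asks the same of the large PVP-coated particles. Slc1a2 rose 10.9-fold (log2 fold change 3.45, SE 0.194) and Sqstm1 2.98-fold (1.57, SE 0.124). Zfand5 (1.08), Ugt1a6 (0.99), Atp6v1b2 (0.86), Gstp1 (0.78), Rab10 (0.72), Vegfa (0.66), Ddit4 (0.65) and Eaf1 (0.65) rose as well. Of the called genes taken by the naming rule, Slc39a10 fell most (-1.28, SE 0.112), followed by Nfix (-0.88), Prrx1 (-0.85) and Fam83d (-0.83). Tmem158 (-0.72) fell as well.

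In PVP75, 149 of 2748 probes (5.42%) were called by limma, 72 higher and 77 lower, of which 37 changed by over 1.5-fold. The call was lost without 1 or more single arrays or without the detection filter for Bmpr2 (-0.76), Pkia (-0.63), Basp1 (-0.63), Il1rap (-0.62), Arsj (-0.60), Cav1 (-0.38), Psma1 (0.53), Psmd2 (0.48), Psmd12 (0.29) and Hspb1 (0.56). The count was 73 without control replicate 3 and 85 without control replicate 4. Chip 1 held 1 control array and chip 2 held 1 PVP75 array, so counts on a chip alone are not given. Tjp1 was not called (log2 fold change -0.06, SE 0.1, adjusted p = 0.808).

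Of 9 NRF2 list genes 4 rose in PVP75 (4 when adjusted over the list alone), with Me1 at 0.62 and Mafg, which encodes a partner of NRF2, at 0.46 beside Sqstm1 and Gstp1 (camera adjusted p = 1.59e-05, and adjusted p = 0.00351 with an estimated correlation). Ephx1 of the same list, named after its values were seen, was at -0.73 (SE 0.586, adjusted p = 0.59), and its probe had lost its signal on PVP75 replicate 3, without which the list gave an adjusted p = 9.39e-07. Of 19 proteasome genes 4 rose (7 when adjusted over the list alone), with Psmb2 at 0.47 (adjusted p = 0.000272, and adjusted p = 0.00669 with an estimated correlation). Of 10 lysosome and autophagy genes 2 rose (4 when adjusted over the list alone), Sqstm1 and Atp6v1b2 (adjusted p = 0.000462, and adjusted p = 0.0452 with an estimated correlation). Of 6 endoplasmic reticulum stress genes Herpud1 rose by 0.60 (2 called when adjusted over the list alone), and the list gave an adjusted p = 0.0231, and adjusted p = 0.195 with an estimated correlation. Chip 1 held 1 control array and chip 2 held 1 PVP75 array, so list tests within a chip are not given for this comparison.

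The citrate-coated particles were compared with control in the same way. In citrate10, Slc1a2 rose 3.24-fold (log2 fold change 1.70, SE 0.183, adjusted p = 1.27e-06), above the control mean on 5 of 5 arrays, and was the 1 probe called by limma. The raw p was under 0.05 for 114 probes, where chance gives 137. Next by p were Lpar2 (-0.47, detected on 2 of 5 citrate10 arrays) and Gla (0.45), which missed the threshold (adjusted p = 0.828 for both). In citrate75, limma called 0 probes, with 237 at a raw p under 0.05, and 13 when array weights were added. The smallest p-values were for Tomm40 (0.68, adjusted p = 0.154), Rbx1 (-0.50, adjusted p = 0.406) and Akr1c12 (0.37, adjusted p = 0.423), none of which passed. Slc1a2, chosen here after its values were seen, was at 0.30 in citrate75 (SE 0.187, adjusted p = 0.714). The 95% interval of a typical log2 fold change reached 0.23 to either side for both particles. Tjp1 was at 0.17 in citrate10 (adjusted p = 0.996) and 0.03 in citrate75 (adjusted p = 0.972).

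In citrate10 the lysosome and autophagy list (median 0.11) and the immediate early list (median 0.13) were called, although 0 members of either were called. Adjusted over the list alone, 1 lysosomal and 0 immediate early genes were called. The list tests gave an adjusted p = 0.0051 and 0.0256, and adjusted p = 0.077 with an estimated correlation for each. In citrate75 the endocytosis list was called with 0 members called (0 when adjusted over the list alone) and a median of 0.13 (adjusted p = 0.0285, and adjusted p = 0.077 with an estimated correlation). Within chip 2 the camera adjusted p was 0.029 for the lysosome list, 0.00766 for the immediate early list and 0.0904 for the endocytosis list. Chip 1 held 1 control array, so whether these shifts recur there was not decided. The endocytosis call was also lost without the chip term.

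The PVP particles moved largely overlapping genes. Of the 72 probes higher in PVP75, 69 were also higher in PVP10, where independent lists would share 14.5, and of the 77 lower ones 74 were also lower, where 16.7 would be shared. None was called in opposite directions. Both of these lists use the same control arrays, which the value for independent lists leaves out. In comparisons that share no array, PVP10 vs citrate10 and PVP75 vs citrate75, 145 of the 180 probes higher in the latter were also higher in the former (36.5 for independent lists). Of the 208 lower ones 175 were also lower (44.7), and 1 probe of each direction was called the opposite way. Across probes, which are not independent replicates, the log2 fold changes of PVP10 and PVP75 correlated at r = 0.765. Unchanged groups simulated against the same controls gave 0.55, and the mean over splits of the controls was 0.651. Their covariance was 0.0725, against 0.00825 in the simulations. Over the 1148 probes called in PVP10, PVP75 changes had a slope of 0.379 on PVP10 changes and the same sign for 90.6%. These probes were chosen by their change against the shared controls, and an unchanged PVP75 simulated against them gave a slope of 0.0252 and the same sign for 54.4%. The same sign was seen for 63.3% in citrate10 and 47.2% in citrate75. In the comparisons that share no array, the slope over the 1148 probes called at 10 nm was 0.391, with the same sign for 85.5%. The correlation there was 0.695 (jackknife SE 0.0896), with 0.598 on chip 1 and 0.536 on chip 2, which held 1 PVP75 array.

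For the pairs with a citrate particle, the covariance was closer to the value simulated for shared controls alone, while r lay below its simulated value. Both groups were unchanged in these simulations, so real changes in either can lower r, and an r below the simulated value does not show opposing profiles. For citrate10 and citrate75, with few or no called probes, r and covariance also lay below it, so the simulations may overstate what shared controls give. PVP10 and citrate10 correlated at r = 0.298 (simulated 0.559, split controls 0.148), with a covariance of 0.0151 against a simulated 0.00793. PVP75 and citrate10 correlated at 0.449 (simulated 0.556, split controls 0.167), with a covariance of 0.0113 against 0.00835. For citrate75 the r was -0.0268 with PVP10 (simulated 0.561, split controls -0.105), 0.207 with PVP75 (simulated 0.584, split controls 0.0138) and 0.287 with citrate10 (simulated 0.561, split controls -0.051). The covariances were -0.00165, 0.00632 and 0.0047, against simulated values of 0.00808, 0.00889 and 0.0081.

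**Figure D4:**
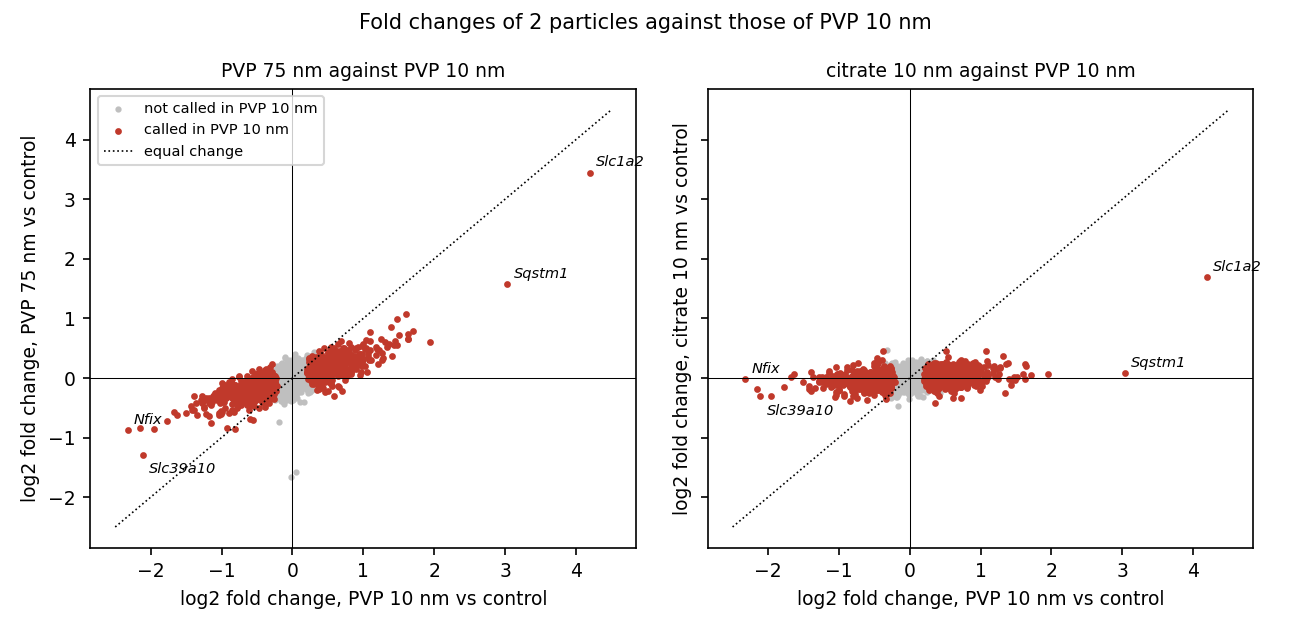
Log2 fold change against control in PVP75 and in citrate10 (vertical axes) by that in PVP10 (horizontal axis), with a point for each tested probe, red where called in PVP10, and a dotted line of equal change. PVP75 changes follow those of PVP10 at a slope of 0.379 (r = 0.765), citrate10 changes correlate at r = 0.298, and the gray points near -1.57 in PVP75 are Rps14 and an unnamed probe, which lost their signal on PVP75 replicate 3.

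The size of PVP-coated particles was compared directly. Every particle was given at 1 ppm, and no group received a coating without particles or dissolved silver. Effects of size and of coating, here and below, therefore cannot be told apart from other traits that go with them at an equal dose. Sqstm1 was 2.75-fold higher in PVP10 than in PVP75 (log2 difference 1.46, SE 0.114) and Lap3 2.53-fold (1.34, SE 0.148). Crebrf (1.03), Ddit4 (0.98), Eaf1 (0.98), the autophagy gene Atg14 (0.96, detected on 1 of 5 PVP75 arrays), Cnih1 (0.95), the endolysosomal tethering gene Vps18 (0.95), Hspb1 (0.92) and Arfgap1 (0.91) were also higher. Nfix (-1.45), Fam83d (-1.32), Prrx1 (-1.11), Epb41l1 (-1.09) and Tmem158 (-1.04) were lower in PVP10. Slc1a2 was 1.68-fold higher in PVP10 (0.75, SE 0.179, adjusted p = 0.00194), with 4 of 5 PVP10 arrays above the PVP75 mean.

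Between the PVP sizes, 768 of 2748 probes were called by limma, 355 higher and 413 lower in PVP10, with 377 on chip 1 alone. Chip 2 held 1 PVP75 array, so no count or list test is given for it. Of 19 proteasome genes 7 were higher, among them Psma2 (0.70) and Psmb2 (0.62), and 0 lower (9 when adjusted over the list alone, camera adjusted p = 0.000397, and adjusted p = 0.0072 with an estimated correlation). Of 10 lysosome genes 5 were higher, among them Sqstm1 (1.46), Gla (0.70) and Lamp2 (0.48), with 6 called when adjusted over the list alone. The lysosome list gave a camera adjusted p = 0.00918, and adjusted p = 0.089 with an estimated correlation. Of 15 cell cycle genes 6 were lower, with Bub1 at -0.49 and Kif2c at least 1.41-fold lower (6 when adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.077 with an estimated correlation). Cbr3 (-0.83), Adm (-0.84), Myc (-0.69) and Tjp1 (-0.30) were also lower in PVP10, the last call being lost without PVP10 replicate 5 or PVP75 replicate 2. Rpl8 was called (-0.24, adjusted p = 0.0444) but was the 1 gene of the 74 taken by the naming rule with opposite directions on the chips. Within chip 1 the camera adjusted p was 0.000399 for the proteasome, 0.00624 for the lysosome list and 0.0601 for the cell cycle list.

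Between the citrate sizes, Slc1a2 was 2.62-fold higher in citrate10 than in citrate75 (1.39, SE 0.174, adjusted p = 2.5e-05), on 5 of 5 arrays without overlap. The GTPase-activating gene Tbc1d20 was lower (-0.44, adjusted p = 0.0364), a call lost without any of 6 single arrays or without the detection filter. With 2 unnamed probes these made 4 calls by limma, 3 higher and 1 lower, beside 376 probes at a raw p under 0.05. The complement gene C1r (-0.39, adjusted p = 0.075) missed the threshold. The count was 1 on each chip alone, 1 to 17 when single arrays were left out and 72 with array weights, and 0 lists were called.

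The coatings were compared at each size. At 10 nm, Sqstm1 was 7.75-fold (2.95, SE 0.11) and Slc1a2 5.65-fold (2.50, SE 0.172) higher under PVP than under citrate. Lap3 (1.88), Eaf1 (1.64), the Golgi trafficking gene Golph3 (1.60) and Zfand5 (1.54) were also higher, and Nfix (-2.30), Fam83d (-1.96), Slc39a10 (-1.81), Il1rap (-1.70), Prrx1 (-1.66) and Ctdspl (-1.30) were lower. At 75 nm, Slc1a2 was 8.83-fold (3.14, SE 0.174) and Sqstm1 2.66-fold (1.41, SE 0.111) higher under PVP, with Ugt1a6 (1.13), Zfand5 (1.13), Rab10 (0.91), Gstp1 (0.81) and Ppid (0.68) also higher. Slc39a10 (-1.09), Fam83d (-0.89), Nfix (-0.87), Prrx1 (-0.87) and the mitotic gene Incenp (-0.62) were lower.

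The coating comparison called 1148 of 2748 probes at 10 nm (557 higher and 591 lower under PVP) and 388 at 75 nm (180 and 208). On chip 1 and chip 2 alone, the counts were 516 and 1017 at 10 nm. At 75 nm the count was 125 on chip 1, while chip 2 held 1 PVP75 array and has no count or list test here. Of 19 proteasome genes 14 were higher at 10 nm (14 when adjusted over the list alone), such as Psmd12 (0.74), and the list gave an adjusted p = 5.32e-05, and adjusted p = 0.00351 with an estimated correlation. At 75 nm 7 were higher (8 when adjusted over the list alone), such as Psmd3 (0.53) and Psmd4 (0.50), with an adjusted p = 0.000302, and adjusted p = 0.00669 with an estimated correlation. Within chip 1 the 75 nm shift of the proteasome had a camera adjusted p = 0.000399. The 10 nm shift had 0.00014 on chip 1 and 0.000432 on chip 2. Of 9 NRF2 list genes 5 were higher at 75 nm (6 when adjusted over the list alone), among them Sqstm1 (1.41), Me1 (0.61) and Mafg (0.51). The camera test gave an adjusted p = 5.32e-05, adjusted p = 0.00351 with an estimated correlation, and 0.000399 within chip 1. At 10 nm 4 were higher and 2 lower (8 when adjusted over the list alone), and the list was not called (adjusted p = 0.0711).

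The lysosome and endoplasmic reticulum stress lists were called upward under PVP at both sizes, and each call was lost with an estimated correlation. Of 10 lysosome genes 6 were higher and 1 lower at 10 nm (8 when adjusted over the list alone, adjusted p = 0.0119, and adjusted p = 0.0995 with an estimated correlation). At 75 nm 3 were higher, among them Sqstm1 (1.41) and Atp6v1b2 (0.58), with 3 called when adjusted over the list alone. The lysosome list there gave a camera adjusted p = 0.0197, and adjusted p = 0.12 with an estimated correlation. Of 6 endoplasmic reticulum stress genes 3 were higher at 10 nm, Canx by 1.05 (3 when adjusted over the list alone, adjusted p = 0.0293, and adjusted p = 0.24 with an estimated correlation), and 2 at 75 nm, Herpud1 by 0.67 and Canx by 0.57 (2 when adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.195 with an estimated correlation). Of 15 cell cycle genes 9 were lower and 1 higher at 10 nm (11 when adjusted over the list alone, adjusted p = 0.0273, and adjusted p = 0.0793 with an estimated correlation). At 75 nm 3 were lower and 1 higher (4 when adjusted over the list alone), and the list was not called (adjusted p = 0.427). The ribosomal list was not called at 75 nm (adjusted p = 0.116), but was without PVP75 replicate 3 (adjusted p = 0.0226). Within chip 1 and chip 2 at 10 nm the adjusted p was 0.0132 and 0.0209 for the lysosome list, 0.0341 and 0.0604 for endoplasmic reticulum stress, and 0.0475 and 0.0473 for the cell cycle. At 75 nm it was 0.0111 for the lysosome list and 0.0949 for endoplasmic reticulum stress on chip 1, and is not given for chip 2, which held 1 PVP75 array. Single genes included Cav1 (-1.08), Rab5a (0.94), Thbd, which was detected on 4 of 5 citrate10 arrays and was at least 1.35-fold lower, the transcription factor gene Klf4 (-0.80, detected on 2 of 5 PVP10 arrays) and Tjp1 (-0.53, adjusted p = 1.71e-05) at 10 nm, and the caveolar gene Cavin1 (-0.47) and the cyclin gene Ccne2 (0.36) at 75 nm.

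The interaction of size and coating asks whether the effect of size differed between the coatings. It did for Sqstm1, whose size effect was larger under PVP by 1.54 (SE 0.157, adjusted p = 3.26e-07), and for Lap3 (1.19), Hspb1 (1.09), Golph3 (1.04) and the endosomal syntaxin gene Stx12 (1.02). It was more negative under PVP for Nfix (-1.43), Epb41l1 (-1.23), Il1rap (-1.13), Fam83d (-1.07), Tcf7l1 (-1.03) and Tjp1 (-0.44, adjusted p = 0.0181), the last call being lost without the detection filter. For Slc1a2 the difference did not pass (-0.64, SE 0.245, adjusted p = 0.0761).

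The interaction was called by limma for 418 of 2748 probes, 193 positive and 225 negative, with 35 on chip 1 alone. Chip 2 held 1 PVP75 array, so no count or list test is given for it. Of 19 proteasome genes 3 were positive, Psmb2 by 0.52 (3 when adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.0641 with an estimated correlation). Of 10 lysosome genes 3 were positive, among them Sqstm1 (1.54) and Ctsl (0.44), with 8 called when adjusted over the list alone. The lysosome list gave a camera adjusted p = 0.0273, and adjusted p = 0.152 with an estimated correlation. Of 15 cell cycle genes 3 were negative, among them Kif2c, whose difference has no measured size because it was detected on 0 of 5 PVP10 arrays (4 when adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.077 with an estimated correlation). Within chip 1 the camera adjusted p was 0.0475 for the proteasome, 0.105 for the lysosome list and 0.0221 for the cell cycle.

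PVP10 was last set against the mean of the other 3 particles. Sqstm1 was 5.38-fold (2.43, SE 0.0913) and Slc1a2 5.20-fold (2.38, SE 0.143) higher, with Lap3 (1.75), Eaf1 (1.44) and Rab10 (1.33), while Nfix (-2.03), Fam83d (-1.83), Prrx1 (-1.58) and the transcription factor subunit gene Taf6 (-1.19) were lower. By limma 1241 of 2748 probes were called, 584 higher and 657 lower, with 728 on chip 1 alone and 1042 on chip 2 alone. Of 19 proteasome genes 15 were higher (15 when adjusted over the list alone, adjusted p = 5.32e-05, and adjusted p = 0.00351 with an estimated correlation), with 7.62e-05 on chip 1 and 0.000432 on chip 2. Of 10 lysosome genes 6 were higher and 1 lower (7 when adjusted over the list alone, adjusted p = 0.00977, and adjusted p = 0.0909 with an estimated correlation), with 0.00548 and 0.0279 within the chips. Of 15 cell cycle genes 9 were lower and 1 higher (10 when adjusted over the list alone, adjusted p = 0.0276, and adjusted p = 0.0793 with an estimated correlation), with 0.0729 and 0.0342 within the chips. Of 6 endoplasmic reticulum stress genes 3 were higher (3 when adjusted over the list alone, adjusted p = 0.0485, and adjusted p = 0.294 with an estimated correlation), with 0.057 and 0.0761 within the chips, and that call was lost without PVP75 replicate 3 (adjusted p = 0.0633). Any difference among the 5 groups was called for 1200 probes.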

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

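The tests of shared controls, of mixed RNA, of array strength, of array labels, of probe names and of probe differences were chosen only after the result was seen. The test of proportional changes and the counts over other splits of the samples were set beforehand. A first test of array strength was set aside for another once its result was seen, and the results of both are given.

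The changes in PVP75 ran the same way as those in PVP10 and were smaller. The control arrays that both comparisons share do not account for it, since comparisons that share no array correlated at 0.695 across probes (jackknife SE 0.0896). Mixing of PVP10 RNA into the PVP75 samples would give every probe of a sample the same share. It stays open, but a single share does not describe every gene. Of the 1148 probes called in PVP10, 11 (0.958%) departed from a single mixing share, whose median was 0.355. That low count says little, since only 418 of the 1148 changed by over 1.5-fold, and departures of small changes could rarely be seen. Among genes with large changes the share was 0.275 for Sqstm1, 0.572 for Slc1a2 and 0.767 for Slc39a10, which a single share does not describe. A lower strength of the same changes, proportional on the log2 scale, stays open as well, with the same limit. From it 15 probes (1.31%) departed, Slc1a2 by the most (1.86 above proportional, adjusted p = 7.18e-09). Most probes could not decide between these explanations, and the particle size that the design names is among the biological explanations that remain.

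PVP75 replicate 3 stood apart from the other arrays, with a score of 17 on the second principal component against -4.85 to 0.565 for the other PVP75 arrays, and 3 of its probes had lost their signal, with log2 differences from the other PVP75 arrays of -9.26 for Rps14, -8.78 for an unnamed probe and -5.09 for Ephx1. A weaker hybridization of the whole array would have lowered all bright probes together, but their median difference was -0.4 log2 units, so it does not account for these 3 losses. For the other 9 probes that deviated by over 1 log2 unit it was not decided. Of these, 88.9% were dimmer on this array, between what was set for either answer. The test set aside, which took all 12 together, had 91.7%. Both used levels after quantile normalization, which gives every array the same distribution, so neither can show a dimming of the whole array. A wrong label among the 5 groups would have moved its slope on the PVP10 profile, which was 0.393, inside the 0.332 to 0.425 of the other PVP75 arrays. What removed the signal of single probes was not tested, and no biological explanation was tested.

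Many transcripts that most cells hold in quantity were not detected, among them Vim, Fth1, B2m and Rplp0, while others such as Rpl23a and Tpt1 were bright. Names that do not belong to the probes would leave ribosomal protein probes at the common rate. These were kept more often than other named probes (40.7% against 14.2%), with an odds ratio of 4.16 (95% interval 2.36 to 7.21). That argues against names wrong throughout, but not against names wrong for a part of the probes. Of 118 genes with several probes and at least 1 kept, only 15.3% had all of them kept. Probes of the same gene that differ in how well they report it would give a low share. Names wrong for a part of the probes would as well, so the share cannot tell these apart and both stay open. No biological explanation was tested.

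Single arrays lay far from the rest of their group for 21 of the 311 groups of values looked at, where chance gives about 1 in 20, or 15.6. Detected probes numbered 2191 on PVP75 replicate 1 (2349 to 2399 on the others) and 2128 on citrate75 replicate 2 (2483 to 2576). The median signal was 85.19 on citrate10 replicate 3 (89 to 90.27). On control replicate 4 the log2 levels were 10.16 for Hspb1 (9.969 to 9.976), 4.65 for Crebrf (4.834 to 4.863), 7.562 for Slc39a10 (7.072 to 7.137) and 5.32 for Plk1 (4.968 to 5.006). On PVP75 replicate 5 they were 6.825 for Epb41l1 (7.232 to 7.379), 6.399 for Cbr3 (6.68 to 6.78) and 8.702 for Tcf7l1 (9.07 to 9.196), and on PVP75 replicate 1 it was 5.064 for Gla (5.508 to 5.61). On PVP10 replicate 5 Phlda1 was at 5.626 (6.088 to 6.261), and on PVP10 replicate 2 Rpl8 was at 12.15 (12.5 to 12.61). On citrate75 replicate 3 Akr1c12 was at 13.58 (13.88 to 13.95), Prrx1 at 9.325 (9.516 to 9.586) and Ctsl at 10.58 (10.49 to 10.51). On citrate75 replicate 2 Psmd3 was at 10.06 (9.777 to 9.843) and Atp6v1b2 at 7.503 (7.873 to 7.982), on citrate75 replicate 1 Rab10 was at 7.698 (7.8 to 7.839), and on citrate10 replicate 3 Tcf7l1 was at 9.183 (9.478 to 9.586).

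The effect of size differed between the coatings, by the interaction test, for 418 probes. The difference, size effect under PVP minus that under citrate, was 1.54 for Sqstm1, 1.19 for Lap3, 1.09 for Hspb1, 1.04 for Golph3, 1.02 for Stx12, 0.517 for Psmb2 and 0.439 for Ctsl. It was -1.43 for Nfix, -1.23 for Epb41l1, -1.13 for Il1rap, -1.07 for Fam83d, -1.03 for Tcf7l1 and -0.437 for Tjp1.

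Other divisions of the arrays gave fewer calls for most counts, but this does not exclude chance. With 100 splits the smallest share that can be seen is 1 in 100. The splits also treat the arrays as separate samples, while the labels do not say whether they came from separate cultures. Of 100 splits of the compared arrays, the real one included, 1 gave as many calls for PVP10 vs control (1148 against at most 828 in other splits), PVP75 vs control (149 against 45), PVP10 vs PVP75 (768 against 331), citrate10 vs citrate75 (4 against 2), PVP10 vs citrate10 (1148 against 501), PVP75 vs citrate75 (388 against 238), PVP10 against the other particles (1241 against 1) and any difference (1200 against 237). For citrate10 vs control 4 of 100 splits gave as many (1 against 1). For the interaction 2 did (418 against 598 in the other). Its splits shuffled the labels of all 4 particles, so they stand for no difference among particles and not for the absence of an interaction. They say nothing on chance for the interaction, and why the other split gave more was not tested. For citrate75 vs control 0 probes were called, so all 100 splits had to give as many, and this count says nothing on chance.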

How the results depend on the processing

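Quantile normalization over the kept probes, the counts and list tests without PVP75 replicate 3, and the comparisons without shared arrays were chosen only after the result was seen. Of the called genes named, Rpl8 between the PVP sizes had opposite directions on the chips alone, and 0 turned in the other processing alternatives or with single arrays left out. Tjp1, where not called, had opposite directions on the chips in PVP75 vs control, citrate75 vs control and PVP75 vs citrate75. Over the processing alternatives, chips alone not counted, 5010 values stayed on the same side of the threshold, 167 fell short and 10 passed newly, and with single arrays left out these were 5762, 322 and 1. Of list results 1266 were the same, 33 weaker, 58 stronger and 3 reversed. Low signal over background limits what can be seen, since only 12.3% of probes were kept. The cause of the changes below was not tested. Chips alone and compared groups alone hold fewer arrays, and no filter adjusts over more probes. Either may lower a count of called probes, but this was not tested and would not cover counts that rose.

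On chip 1 alone, where the lone control array is assumed to vary like the others, the counts of called probes were 367 for PVP10 vs control (1148 with all arrays), 6 for PVP75 vs control (149), 377 for PVP10 vs PVP75 (768), 1 for citrate10 vs citrate75 (4), 516 for PVP10 vs citrate10 (1148), 125 for PVP75 vs citrate75 (388), 35 for the interaction (418), 728 for PVP10 against the other particles (1241) and 540 for any difference (1200). On chip 2 alone they were 44 for PVP75 vs control, 344 for PVP10 vs PVP75, 1 for citrate10 vs citrate75, 14 for PVP75 vs citrate75 and 147 for the interaction. Of the calls on chip 1 alone, 366 of 367 for PVP10 and 5 of 6 for PVP75 were also called with all arrays, and on chip 2 alone 991 of 1047 and 36 of 44. Each chip is a part of all arrays, so this overlap is not an independent check. Without a filter on dim probes the counts were 68 for PVP75 vs control, 1 for citrate10 vs citrate75, 203 for PVP75 vs citrate75 and 234 for the interaction. With the compared groups alone they were 45, 2 and 254 for the first 3 of these.

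Array weights gave 13 calls for citrate75 vs control (0 otherwise) and 72 for citrate10 vs citrate75. For the latter, no background correction gave 9 (55.6% higher, against 75% otherwise), an offset of 50 gave 8 (50% higher), the authors' normalized values 9 (55.6% higher), detection on all 24 arrays 9, and no chip term or a random chip block 8. Leaving out single arrays gave 1 to 17 for citrate10 vs citrate75, with 17 without citrate75 replicate 3, 7 without citrate75 replicate 2, 2 without citrate10 replicate 1, and 1 without citrate75 replicate 1 or 5 or citrate10 replicate 3 or 4. It gave 73 (without control replicate 3) to 151 for PVP75 vs control, with 85 without control replicate 4. The ranges were 987 to 1094 for PVP10 vs control, 1 to 1 for citrate10 vs control, 0 to 0 for citrate75 vs control, 663 to 778 for PVP10 vs PVP75, 1060 to 1098 for PVP10 vs citrate10, 284 to 431 for PVP75 vs citrate75, 350 to 487 for the interaction, 1143 to 1270 for PVP10 against the other particles and 1106 to 1238 for any difference.

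The replicate block gave 1127 calls for PVP10 vs control, 139 for PVP75 vs control, 763 for PVP10 vs PVP75, 1139 for PVP10 vs citrate10, 403 for PVP75 vs citrate75 and 418 for the interaction. Deviations of same-numbered arrays correlated between -0.172 and 0.264, with at most 3 of 5 pairs over 0.1 (PVP75 vs citrate75) and no comparison with every pair over 0.1, so the numbers were not taken to pair the samples.

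The number of called lists was 5 for PVP10 vs control, and 3 with detection on all 24 arrays, 1 with an estimated correlation and 8 with fry. For citrate10 vs control it was 2, and 4 with no filter, 1 with the replicate block and 0 with an estimated correlation. For citrate75 vs control it was 1, and 0 without the chip term or with an estimated correlation. For PVP10 vs PVP75 it was 3, and 7 with no filter, 1 with an estimated correlation and 7 with fry. For citrate10 vs citrate75 it was 0, and 4 with no filter, 1 with detection on all 24 arrays and 3 with fry. For PVP10 vs citrate10 it was 4, and 8 with no filter, 2 with detection on all 24 arrays, 1 with an estimated correlation and 10 with fry. For PVP75 vs citrate75 it was 4, and 7 with no filter, 2 with detection on all 24 arrays, 2 with an estimated correlation and 7 with fry. For the interaction it was 3, and 5 with no filter, 0 with an estimated correlation and 5 with fry. For PVP10 against the other particles it was 4, and 7 with no filter, 2 with detection on all 24 arrays, 1 with an estimated correlation and 9 with fry. The metal handling list turned downward with fry, with an adjusted p = 0.000732 for PVP10 vs control, 0.000984 for PVP10 vs citrate10 and 0.00594 for PVP10 against the other particles.

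The correlation of PVP10 and PVP75 was 0.686 with no filter and 0.651 with split controls. Split controls gave 0.148 for PVP10 and citrate10, 0.167 for PVP75 and citrate10, 0.0138 for PVP75 and citrate75, and -0.051 for citrate10 and citrate75, where the sign turned. For PVP10 and citrate75 no filter gave 0.0863 in place of -0.0268.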

Other observations

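The test of a size effect shared by both coatings was set before its result was seen, and no test in this part was chosen only after the result was seen.

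A hypothesis that 10 nm particles of both coatings moved the same probes relative to 75 nm particles was tested on comparisons that share no array. The log2 differences of PVP10 vs PVP75 and of citrate10 vs citrate75 correlated at r = 0.25 across probes (jackknife SE 0.113), with 0.262 on chip 1 and 0.0501 on chip 2. Of the 768 probes called between the PVP sizes, 68% had the same sign between the citrate sizes. A shared size effect may exist but is weak. The value on chip 2 was close to 0, but that chip held 1 PVP75 array, so it decides little.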
